A study of Homo sapiens with 9 samples.

How the data were processed

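Poly(A) RNA of A375 melanoma cells was sequenced in 9 libraries, 3 each from cells overexpressing GADD45B, cells overexpressing HOPX and WT cells. Per the labels' protocols, polyadenylated RNA was fragmented, copied into strand-marked cDNA, joined to adapters that carry unique molecular identifiers, and sequenced as read pairs on an Illumina NovaSeq. Per the submitters' processing notes, the tools used included cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR; the part each played, the genome build and the annotation are not given in the sources used here. Per the file headers, the deposited table gives each gene an FPKM value and a raw read count per library, with the Ensembl identifier, symbol, position and annotation terms. The FPKM values were scaled by the authors to transcript length and library total, per the file headers, and the counts carry no scaling.

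The table analysed here held 99 genes in the order of their Ensembl identifiers. They fall within the lowest 107 identifiers of GENCODE 29, and 8 identifiers of that span were not used here. All 99 identifiers matched GENCODE 29, which supplied exon lengths (the union of exons), GC content and overlaps between genes, while names and positions are those of the table. Because the table is a small part of each library, its summed counts are not library totals. Relative depth was therefore recovered from the ratio of count to FPKM over the 80 genes with more than 100 counts in every library; 99.7% of the ratios lay within 1% of the library's value. Relative depth ran from 0.947 to 1.046. Dividing by exon length gave implied totals of 51700000 to 57100000, and 81.1% of the single-gene totals lay within 2% of these. Totals refer to whatever unit the authors counted, read pairs or molecules.

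The test planned before the data were examined was limma on log2(FPKM + 1), on the assumption that the table held FPKM only. Since it also held counts, edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on those counts became the main test, a choice made after the units were seen and before any test was run, and the limma fit (limma 3.58.1) was kept as an alternative. All 9 libraries entered a single fit with a mean per group and the recovered depth as library size. Genes with a mean FPKM of at least 1 over all libraries were tested, 72 in number, and 27 lay below. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 72 genes, with a threshold of 0.05. The fit had 11.7 prior degrees of freedom. SDs of FPKM are over 3 libraries and fold changes come from the counts. On simulated counts with 18 of 72 genes changed, in the design of GADD45B over WT (50 simulations), the test recovered 52% of genes changed 1.25-fold, 96% of those changed 1.5-fold and 100% of those changed 2-fold, and 4.49% of its calls were false. The simulated genes were independent, with known depth and no library trend on length or GC content. These shares therefore leave out the scaling and trend uncertainty of the real libraries.

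The genes named were set by a rule fixed before the data were examined: up to 10 rises and 10 falls against WT with the largest change among genes past the threshold whose groups did not overlap. It took 5 each way for HOPX over GADD45B and 5 each way for genes past the threshold in both comparisons with WT. It added up to 4 members of each gene list in each comparison, and the overexpressed genes with their family members, without genes that have clone-style names. A gene that the rule takes is not reported here, although the totals count it. The 30 gene lists were fixed at the same time; none had 5 tested members, so set tests could not be run. Annotation terms of the table (GO, KEGG and Reactome) with at least 5 tested genes were tested with Fisher's exact test against the 72 tested genes (scipy 1.17.1). Chance agreement between both comparisons with WT was simulated with unchanged groups against the same controls (100 simulations). Correlations across genes were tested with 10000 permutations.

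Alternatives planned before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, a fit of the 6 libraries compared, a robust prior, the replicate number as a block, a minimum change of 2-fold, and each library left out in turn. Chosen after seeing the data were DESeq2 1.42.0, TMM scaling, and the removal of per-library linear trends on exon length, GC content or both; limma on log2(FPKM + 1) became an alternative as described above. Median-of-ratios, TMM and quantile scaling were estimated from the 72 tested genes and so assume that most of these are unchanged, whereas the recovered depth assumes that library totals are comparable. Within every group, counts of the replicates differed by more than sampling noise (chi-square per gene 7.84 to 59.3), so no library was counted as a repeat of another. The labels give no batch or date.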

Results

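RNA was sequenced from 9 samples of A375, a human malignant melanoma cell line, in 3 groups of 3 libraries. One group overexpressed GADD45B, a stress-inducible gene of the growth arrest and DNA damage family. Another overexpressed HOPX, which encodes a small homeodomain protein that does not bind DNA by itself, and the last was wild type (WT). The comparisons ask which transcripts differ between each overexpression group and WT. The labels give WT as the only control and name no vector control. Effects of delivering a gene, which both overexpression groups could share, thus cannot be told apart from effects of GADD45B or HOPX. The table analysed here held 99 genes in order of Ensembl identifier, with an FPKM value and a read count for each gene in each library. GADD45B, HOPX, GADD45A and GADD45G are not among those 99 genes, so the level of the overexpressed transcripts, which would check the labels, was not analysed here. Summed counts over the 99 genes ran from 218737 to 260592 per library, or 0.423% to 0.464% of the library totals. Those totals, implied by the FPKM values, were 51700000 to 57100000. Of the 99 genes, 72 had a mean FPKM of at least 1 over the 9 libraries and were tested. The median tested gene had a mean count of 1938 and the lowest 322.9, so counting error was small beside the variation between libraries, a biological coefficient of variation of 10.7%. On the principal component with the most variance (48.7%), the GADD45B libraries lay from -1.49 to -1.13 and the WT libraries from 0.74 to 1.32, with HOPX replicates 1 and 3 at 0.67 and 0.86 but HOPX replicate 2 apart from them at -0.76. On the next component (25.6%) the HOPX libraries lay from 0.61 to 1.33, above the other libraries (-0.94 to 0.12). The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

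Overexpression of GADD45B went with lower transcript levels of SPPL2B, BAD and CROT, the largest changes against WT past the threshold among the 72 tested genes. SPPL2B, an intramembrane aspartyl protease of the signal peptide peptidase family, fell from 2.24 ± 0.261 FPKM in WT to 0.957 ± 0.158 FPKM (SD, n = 3 in each group). BAD, which encodes a pro-apoptotic BH3-only protein, fell from 11.6 ± 2.28 to 5.78 ± 1.74 FPKM (SD, n = 3). CROT, the peroxisomal carnitine octanoyltransferase, fell from 1.51 ± 0.130 to 0.824 ± 0.0799 FPKM (SD, n = 3). The few rises were smaller: MCUB, an inhibitory subunit of the mitochondrial calcium uniporter, went from 4.11 ± 0.268 to 5.47 ± 0.659 FPKM (SD, n = 3).

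In edgeR's quasi-likelihood test the log2 fold change of SPPL2B was -1.23 (SE 0.22, Benjamini-Hochberg adjusted p = 0.000854), a fold of 0.428. The same test gave -1.01 for BAD (SE 0.27, adjusted p = 0.00589) and -0.86 for CROT (SE 0.16, adjusted p = 0.000854). NIPAL3, a membrane protein of the NIPA family, had the smallest adjusted p in edgeR's test, 0.000148, with a log2 fold change of -0.62 (SE 0.09), from 15.9 ± 0.904 FPKM in WT to 10.4 ± 1.297 FPKM. Decreases of similar size were found for SARM1, an NAD-cleaving TIR-domain protein (-0.63), the cationic amino acid transporter SLC7A2 (-0.58), FAM214B (-0.57), the chromatin regulator KMT2E (-0.56), KRIT1, the gene of a familial cerebral cavernous malformation (-0.56), and the homologous recombination gene RAD52 (-0.53). Among the 4 genes that rose were MCUB (0.41), FUCA2, a secreted fucosidase (0.30), and the surface glycoprotein CD99 (0.30). In each of the genes named so far in this comparison, the 3 GADD45B libraries lay entirely above or entirely below the 3 WT libraries, which the rule for naming genes required.

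In total 25 of 72 genes passed an adjusted p of 0.05 against WT, 4 higher and 21 lower, and 2 of them (SPPL2B and BAD) changed at least 2-fold. The 3 libraries of the groups did not overlap in 36 of the 72 genes, or 50%, against 10% by chance for a single gene, and in 24 of the 25 genes past the threshold. The genes share the same libraries and depth factors, so an offset of a library can separate many at once and the excess is not a test. The split changed with how libraries were scaled: median-of-ratios factors, which centre the median change of the tested genes near 0, raised the log2 fold changes between these groups by 0.12. With them 10 genes were higher and 16 lower, and 20 of the 25 genes were still past the threshold. TMM scaling gave 8 higher and 16 lower, and quantile normalization with limma 11 higher and 9 lower. Leaving out 1 library ended 5 named calls in edgeR's test. BAD lost its call without GADD45B replicate 2 (adjusted p = 0.0607) and FUCA2 without GADD45B replicate 1 or WT replicate 2 (0.0512 and 0.115). RAD52 lost it without GADD45B replicate 3 or WT replicate 2 (0.0536 and 0.0604). MCUB lost it without GADD45B replicate 3, WT replicate 2 or WT replicate 3 (0.0536 to 0.0995) and SARM1 without GADD45B replicate 1, WT replicate 1 or WT replicate 2 (0.0759 to 0.137). FUCA2, SARM1 and MYCBP2, a decrease shared with HOPX overexpression, also lost their calls when a trend of counts on exon length was removed from each library (adjusted p = 0.126, 0.0693 and 0.0886). SARM1 lost its call with median-of-ratios and TMM scaling too (adjusted p = 0.0742 and 0.0599).

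**Figure D1:**
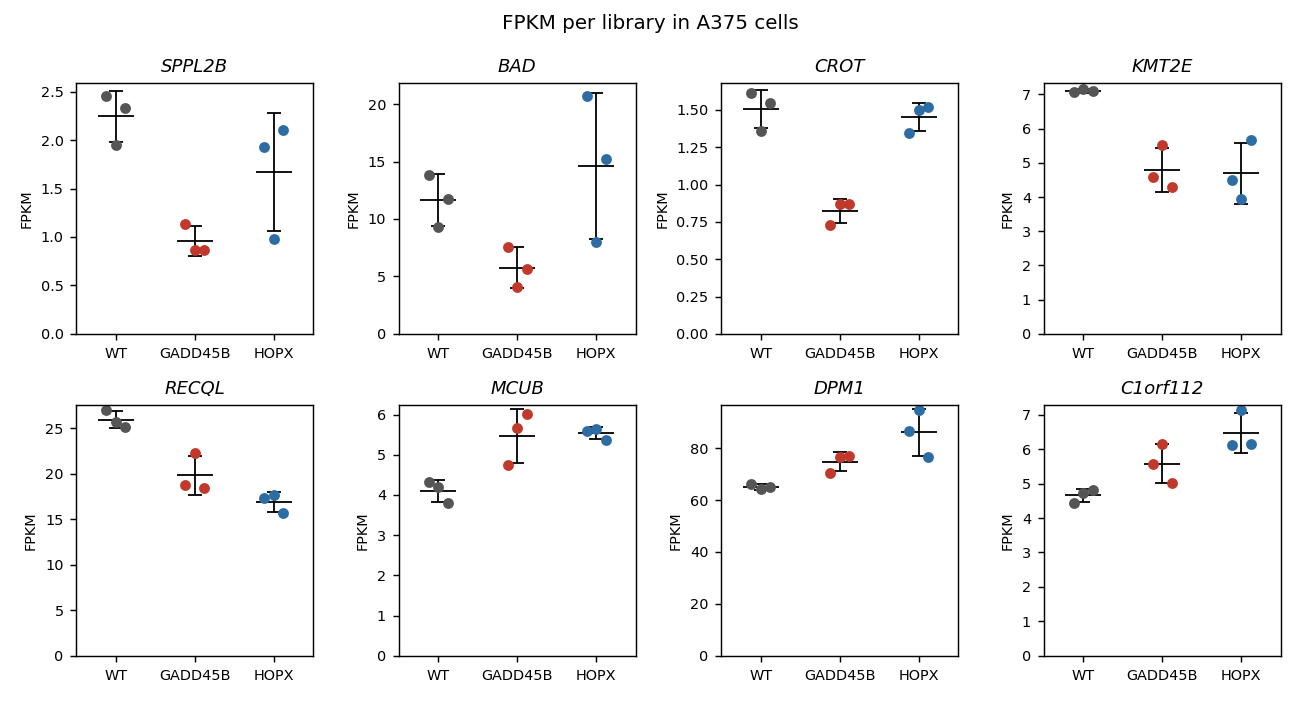
FPKM (vertical axis) of 8 named genes in each of the 9 A375 libraries, grouped as WT, GADD45B overexpression and HOPX overexpression; points are libraries, horizontal bars are group means and error bars are 1 SD (n = 3). SPPL2B, BAD and CROT were lower in the 3 GADD45B libraries than in WT, and BAD ranged from 8.00 to 20.7 FPKM over the HOPX libraries.

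HOPX overexpression went with lower RECQL and KMT2E and with higher C1orf112, MCUB and DPM1 transcripts, all by less than 2-fold. RECQL, a RecQ-family DNA helicase, fell from 25.9 ± 0.960 FPKM in WT to 16.9 ± 1.07 FPKM (SD, n = 3), and KMT2E fell from 7.11 ± 0.0557 to 4.69 ± 0.885 FPKM. C1orf112 rose from 4.66 ± 0.196 to 6.47 ± 0.590 FPKM, and MCUB from 4.11 ± 0.268 to 5.54 ± 0.146 FPKM (SD, n = 3). DPM1, the catalytic subunit of dolichol-phosphate mannose synthase, rose from 65.0 ± 1.04 to 86.0 ± 9.06 FPKM.

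By edgeR's quasi-likelihood test the log2 fold change of RECQL was -0.62 (SE 0.08, Benjamini-Hochberg adjusted p = 6.17e-05) and that of KMT2E -0.60 (SE 0.11, adjusted p = 0.00167). Among the rises the same test gave 0.47 for C1orf112 (SE 0.11, adjusted p = 0.0032), 0.40 for DPM1 (SE 0.08, adjusted p = 0.00167) and 0.34 for the histone demethylase KDM1A (SE 0.07, adjusted p = 0.00204). The other rises were MCUB (0.43), the holocytochrome c synthase HCCS (0.38), CD99 (0.30), the iron-sulfur cluster assembly factor CIAPIN1 (0.26) and the actin-binding protein LASP1 (0.24). The other decreases were VPS50, a subunit of an endosomal recycling complex (-0.49), the ubiquitin ligase MYCBP2 (-0.47), KRIT1 (-0.42), the R2TP co-chaperone RPAP3 (-0.38), CFLAR (-0.36), the ubiquitin ligase ANKIB1 (-0.34) and IBTK, a cullin adaptor that inhibits Bruton tyrosine kinase (-0.32). All 17 of these genes had HOPX libraries that did not overlap the WT libraries.

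The 17 genes past the threshold divided into 8 higher and 9 lower, and 26 of the 72 genes, or 36.1%, had groups that did not overlap, against 10% by chance for a single gene. Here too the genes share their libraries, so the excess is not a test. Median-of-ratios scaling lowered these log2 fold changes by 0.01 and gave 8 higher and 10 lower genes. In edgeR's test, leaving out HOPX replicate 1 ended the calls of MCUB, HCCS, CIAPIN1, LASP1, VPS50, CFLAR and IBTK (adjusted p = 0.0604 to 0.193). Leaving out WT replicate 2 ended those of MCUB, HCCS, CIAPIN1, LASP1 and VPS50 (0.0579 to 0.185), and leaving out WT replicate 3 ended those of MCUB, CIAPIN1, LASP1, VPS50, CFLAR and ANKIB1 (0.0671 to 0.173). Further losses were CFLAR without WT replicate 1 (adjusted p = 0.181), CIAPIN1 without HOPX replicate 2 (0.0805), VPS50 without HOPX replicate 3 (0.0982) and LASP1 without GADD45B replicate 1 or 3 (0.0579 and 0.0624). Removing a trend on exon length from each library took DPM1, the tested gene with the shortest exon length, to 0.07 (edgeR adjusted p = 0.549). It took CFLAR, the tested gene with the longest exon length, to -0.03 (adjusted p = 0.898). The removal also ended the calls of MCUB, HCCS, CIAPIN1 and VPS50 (0.0675 to 0.151).

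Directly compared, cells overexpressing HOPX had more BAD and CROT transcript than cells overexpressing GADD45B. BAD stood at 14.6 ± 6.36 FPKM under HOPX, with 8.00 FPKM in the outlying HOPX replicate 2, against 5.78 ± 1.74 FPKM under GADD45B, and CROT at 1.45 ± 0.0964 against 0.824 ± 0.0799 FPKM (SD, n = 3 in each group). SLC25A13, the mitochondrial aspartate-glutamate carrier citrin, was at 8.45 ± 0.273 FPKM under HOPX, 5.76 ± 0.740 under GADD45B and 8.29 ± 0.0664 in WT. The nonsense-mediated decay helicase UPF1 and the spindle checkpoint gene MAD1L1 were also higher under HOPX than under GADD45B.

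In edgeR's quasi-likelihood test the log2 differences, HOPX over GADD45B, were 1.33 for BAD (SE 0.27, Benjamini-Hochberg adjusted p = 0.00241), 0.81 for CROT (SE 0.16, adjusted p = 0.00241) and 0.55 for SLC25A13 (SE 0.11, adjusted p = 0.00241). They were 0.48 for UPF1 (SE 0.10, adjusted p = 0.00456) and 0.65 for MAD1L1 (SE 0.19, adjusted p = 0.0282). Against WT, HOPX overexpression left BAD at 0.33 (SE 0.26), CROT at -0.05 (SE 0.16) and SLC25A13 at 0.03 (SE 0.11), none past the threshold in edgeR's test (adjusted p = 0.357, 0.884 and 0.885). SPPL2B passed at 0.80 (SE 0.22, edgeR adjusted p = 0.0213), although the HOPX library with 0.980 FPKM (replicate 2) lay among the GADD45B libraries, and lost that call with median-of-ratios and TMM scaling (adjusted p = 0.0799 and 0.0868). Of 72 genes, 12 passed the threshold in edgeR's test, 12 higher and 0 lower under HOPX, while 20 higher and 3 lower had an unadjusted p under 0.05, and DESeq2 gave 7 higher and 0 lower.

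These counts changed with the scaling. Median-of-ratios factors come from the 72 tested genes and centre their median log2 change (0.01 against 0.14), so the split of higher and lower genes under them does not tell which scaling is right. They lowered these log2 fold changes by 0.13 and left 3 genes higher (BAD, CROT and SLC25A13) and 3 lower (among them RECQL and WDR54, with WDR54 chosen after its values were seen). TMM scaling left 3 and 1, and quantile normalization with limma 1 and 3. UPF1 and MAD1L1 did not pass in edgeR's test after median-of-ratios scaling (adjusted p = 0.0549 and 0.162) or TMM scaling (0.0614 and 0.143). MAD1L1 also lost its call without GADD45B replicate 1, GADD45B replicate 2, HOPX replicate 1, HOPX replicate 3 or WT replicate 2 (0.0508 to 0.0806). A fit of the 6 libraries of these groups alone gave 5 genes, as did leaving out GADD45B replicate 3 or HOPX replicate 1, while leaving out GADD45B replicate 1 gave 7 and leaving out HOPX replicate 2 gave 20.

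RECQL, KMT2E, RPAP3, MYCBP2, KRIT1, IBTK and ANKIB1 fell and CD99 and MCUB rose under either overexpressed gene, against the same WT libraries. KMT2E fell by 0.56 under GADD45B and fell by 0.60 under HOPX on the log2 scale, RPAP3 fell by 0.38 under each, and CD99 rose by 0.30 under each. RECQL fell by 0.39 under GADD45B and fell by 0.62 under HOPX. These 9 genes were past the threshold in both comparisons and 0 genes passed in opposite directions. Another 16 genes were past it only in the GADD45B comparison, 8 only in the HOPX comparison and 39 in neither. These classes changed with the scaling: with median-of-ratios and with TMM factors, DPM1, C1orf112, KDM1A and HCCS also passed under GADD45B and NIPAL3 under HOPX, so 14 genes were shared under each, 12 and 10 passed only under GADD45B and 4 and 3 only under HOPX. Whether a gene differs between the overexpression groups was tested only by their direct comparison: 6 of the 16 genes passed it, among them BAD, CROT, SPPL2B, SLC25A13 and NIPAL3, as did LASP1 and CIAPIN1 of the 8. With median-of-ratios scaling BAD, CROT and SLC25A13 kept that call, while SPPL2B, NIPAL3, LASP1 and CIAPIN1 lost it (edgeR adjusted p = 0.0549 to 0.361).

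Independent lists of these lengths would share 0.444 higher and 2.63 lower genes. Unchanged groups simulated against the same controls (100 simulations) seldom reach the threshold, so the number of genes they share (0.01 higher and 0 lower on average) does not measure agreement. Across the 72 genes, which are not independent replicates, the fold changes of both comparisons correlated at r = 0.64 (Spearman 0.70), against a mean r of 0.51 (95% range 0.30 to 0.68) and a mean Spearman correlation of 0.47 (0.30 to 0.62) for unchanged groups sharing 3 controls. The covariance was 0.0527 against a simulated 0.00827 (0.00371 to 0.0135), a difference of 0.0444. The simulated counts held no library trend on length or GC content, so these ranges leave out agreement that such trends could add. With 3 WT libraries the controls could not be split so that each part kept a pair, so part of the excess may come from the shared controls, and r was 0.458 without HOPX replicate 2.

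**Figure D2:**
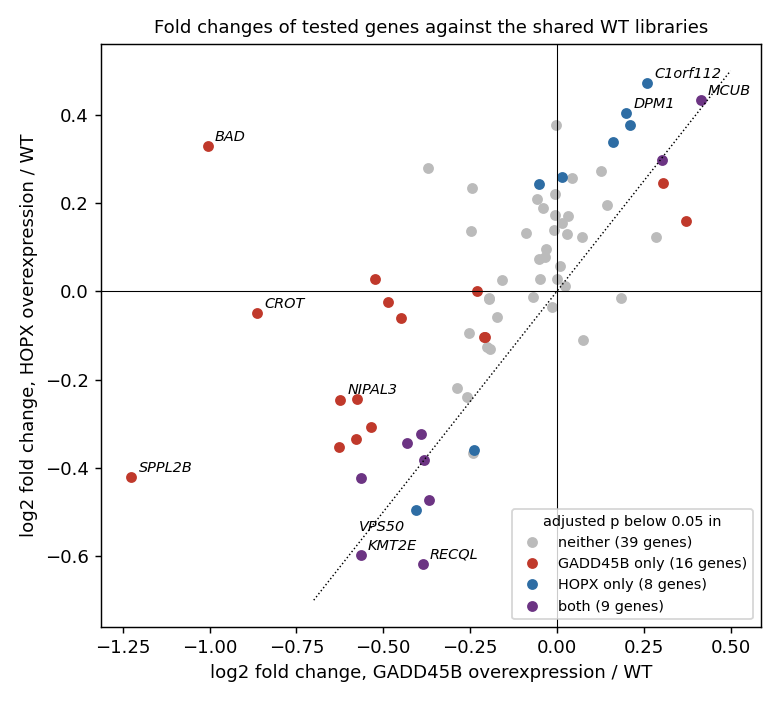
Log2 fold change against WT of 72 genes under GADD45B overexpression (horizontal axis) and HOPX overexpression (vertical axis); each point is a gene, coloured by the comparison in which its adjusted p was below 0.05, and the dotted line marks equal change. KMT2E and MCUB lie near that line, while BAD, CROT and SPPL2B lie far to the left of it.

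Genes with a long exon length (the union of annotated exons) tended to be lower, and genes with a short one higher, in both overexpression groups than in WT. The median exon length was 6824 bp for the genes lower under GADD45B and 8722 bp for those lower under HOPX, such as KMT2E, MYCBP2 and VPS50, against 4239 bp for the genes higher in each comparison, such as CD99 and MCUB, and 5350 bp for genes past no threshold. Across the 72 genes, which are not independent replicates, the Spearman correlation of log2 fold change with exon length was -0.48 for GADD45B over WT and -0.54 for HOPX over WT (Pearson -0.36 and -0.52). Both used the same WT libraries, so they are not independent of each other. Each had a permutation p of 1e-04, the smallest that the permutations can give, and 3e-04 after Benjamini-Hochberg adjustment over 6 relations. For HOPX over GADD45B it was -0.04 (Pearson -0.09, permutation p = 0.748, adjusted p = 0.748). The correlations with GC content were 0.08, 0.23 and 0.21 in the same order (Pearson -0.10, 0.22 and 0.36; permutation p = 0.526, 0.0563 and 0.0818; adjusted p = 0.631, 0.113 and 0.123). With the length trend of each library removed, edgeR's test kept 20 of the 25 calls under GADD45B and 11 of the 17 under HOPX.

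**Figure D3:**
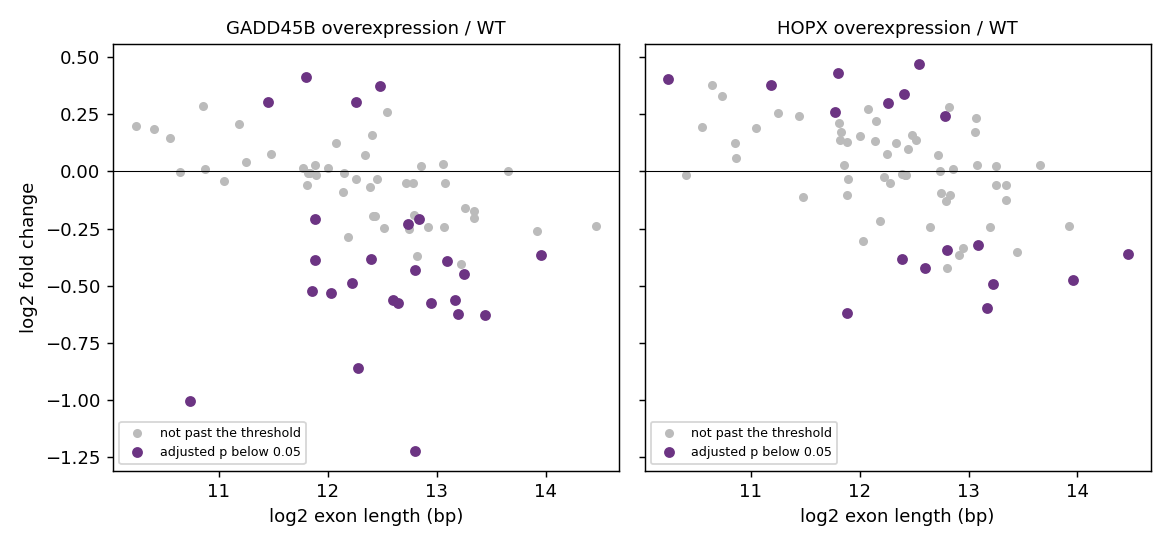
Log2 fold change against WT (vertical axis) by log2 exon length in bp (horizontal axis) for the 72 tested genes under GADD45B overexpression (left) and HOPX overexpression (right); each point is a gene, in purple where its adjusted p was below 0.05. Fold changes against the shared WT libraries fell with length in both groups, with Spearman correlations of -0.48 and -0.54.

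Of the gene groups chosen for melanoma and for these regulators, 3 had members among the tested genes, 1 gene each, so that a p adjusted over the list alone equals the unadjusted p. The pro-apoptotic group was represented by BAD, whose decrease under GADD45B has an adjusted p of 0.00589 over all genes in edgeR's test and 0.00139 adjusted over the list alone. From the anti-apoptotic group CFLAR, the caspase-8 inhibitor c-FLIP, was tested. CFLAR fell under HOPX from 1.40 ± 0.180 to 1.09 ± 0.0433 FPKM (SD, n = 3; edgeR adjusted p = 0.0321 over all genes, 0.00708 adjusted over the list alone). Its log2 fold change under GADD45B was -0.24 (SE 0.12, edgeR adjusted p = 0.119 over all genes, 0.0579 adjusted over the list alone). CYP51A1, the lanosterol demethylase of the cholesterol synthesis group, had log2 fold changes of 0.21 under HOPX (SE 0.09, edgeR adjusted p = 0.0936 over all genes, 0.0299 adjusted over the list alone). Under GADD45B it was -0.06 (SE 0.09, edgeR adjusted p = 0.717 over all genes, 0.527 adjusted over the list alone). In the direct comparison CYP51A1 was higher under HOPX by 0.27 (SE 0.09, edgeR adjusted p = 0.0479 over all genes, 0.00775 adjusted over the list alone) and lost that call with median-of-ratios scaling (adjusted p = 0.361). The other 27 groups, among them p53 targets, pigmentation genes and the markers of RNA quality and of other cell types, had no member in the table and were not analysed here. Fisher's exact tests of the annotation terms with at least 5 tested genes (27 terms, 135 tests) gave 0 terms with an unadjusted p under 0.05, and the smallest adjusted p was 1. All terms of that size came from GO. Among them was a placeholder without a name, held by 12 tested genes. BAD and SPPL2B were among its genes and counted toward no named term, so these tests do not cover their annotation.

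The positions of these genes are those of the deposited table, whose genome build is not given in the sources used here. Its strands equal those of GENCODE 29 on GRCh38 for 99 of 99 genes, and both gene ends lie within 1000 bp for 86. SPPL2B (ENSG00000005206) lies on chromosome 19 from 2328615 to 2355095 on the plus strand, and BAD (ENSG00000002330) on chromosome 11 from 64269830 to 64284665 on the minus strand. On chromosome 7, CROT (ENSG00000005469) spans 87345664 to 87399794 and KMT2E (ENSG00000005483) spans 105014190 to 105114361, both on the plus strand, with SLC25A13 (ENSG00000004864) on the minus strand from 96120220 to 96322147. RECQL (ENSG00000004700) lies on chromosome 12 from 21468910 to 21501669 and DPM1 (ENSG00000000419) on chromosome 20 from 50934867 to 50958555, both on the minus strand. All of these are protein-coding genes in GENCODE 29. Exons of some named genes overlap other annotated genes there, so their counts are uncertain where reads could be assigned to either. On the same strand the larger overlaps were 2972 bp for KRIT1, 2943 bp for CYP51A1, 1048 bp for SPPL2B, 495 bp for SARM1 and 445 bp for CFLAR. On the opposite strand they were 4706 bp for SARM1, 2853 bp for MYCBP2, 2265 bp for CFLAR, 1566 bp for RECQL, 1388 bp for C1orf112, 684 bp for FUCA2, 456 bp for LASP1 and 404 bp for BAD. The libraries marked strand, but whether the counting used it is not given in the sources used here. CD99 has 1 named pseudogene and CYP51A1 has 3, so reads could also be shared with those copies.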

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

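The fits with DESeq2, TMM scaling and the length and GC trends were chosen after the results were seen. Limma on log2(FPKM + 1), planned as the main test, became an alternative once counts were seen, before any test. Counts of genes past the threshold are given as total, higher and lower where needed; unless stated, the cause of a change was not tested. Requiring a 2-fold change left 2, 0 and 2 genes for GADD45B over WT, 0, 0 and 0 for HOPX over WT, and 1, 1 and 0 for HOPX over GADD45B. With median-of-ratios scaling, GADD45B over WT had 10 higher genes and HOPX over GADD45B had 6 (3 higher, 3 lower); with TMM 8, and 4 (3 and 1); with quantile normalization 11 higher and 9 lower, and 4 (1 and 3). A mean FPKM of at least 5, which tests 45 genes, left 12 lower genes for GADD45B and gave 1 lower gene for HOPX over GADD45B. HOPX over GADD45B fell to 5 genes, all 5 higher, in a fit of its 6 libraries, and to 7, all 7 higher, with DESeq2. Removing the length trend gave 5 higher genes for HOPX over WT and 1 lower for HOPX over GADD45B. Removing the GC trend gave 26 genes for HOPX over WT, 14 of them lower, and 1 lower for HOPX over GADD45B, and removing both gave 26 for HOPX over GADD45B (23 higher, 3 lower). With each library left out in turn, GADD45B over WT ranged from 17 to 34 genes (2 to 7 higher, 15 to 27 lower) and HOPX over WT from 10 to 23 (4 to 11 higher, 6 to 12 lower). HOPX over GADD45B ranged from 5 to 20 (5 to 18 higher, 0 to 2 lower), and the correlation of both fold changes from 0.458 to 0.699. The extremes came without WT replicate 2 (17) and HOPX replicate 2 (34), and without HOPX replicate 1 (10) and HOPX replicate 3 (23). For HOPX over GADD45B they came without GADD45B replicate 3 or HOPX replicate 1 (5) and HOPX replicate 2 (20). Without WT replicate 3, HOPX over WT had 11 genes (5 higher), without WT replicate 2 it had 4 higher, and without GADD45B replicate 2 HOPX over GADD45B had 1 lower. Same-numbered libraries deviated together for numbers 1 and 2 (r from 0.29 to 0.50) but not for number 3 (-0.22 to -0.04). Of 9 libraries, 5 correlated best with their own number. Within numbers 1 and 2 a shared effect is possible. The replicate block gave 33, 22 and 17 genes, with 1 lower in HOPX over GADD45B. The prior degrees of freedom rose from 11.7 to 143 after GC removal, 207 after removal of both trends, 296 without HOPX replicate 2 and infinity under the block, so those larger counts rest on p-values that use almost no gene-specific spread. Of the values of named genes under the alternatives, 373 of 402 kept direction and call for GADD45B over WT, 358 of 406 for HOPX over WT and 102 of 118 for HOPX over GADD45B. Another 28, 47 and 16 lost the call without reversing. SLC7A2 under GADD45B (0.027) and CFLAR under HOPX (0.051) reversed with quantile normalization. There the calls of BAD, CROT, SARM1, RAD52, RPAP3 and MYCBP2 under GADD45B also ended, as did those of DPM1, CD99, LASP1 and VPS50 under HOPX (adjusted p = 0.101 to 1) and all 5 named for HOPX over GADD45B (BAD, CROT, SLC25A13, UPF1 and MAD1L1; 0.0542 to 0.229). The robust prior ended the calls of BAD (adjusted p = 0.0751 for GADD45B over WT, 0.06 for HOPX over GADD45B) and SARM1 (0.0528), DESeq2 those of CIAPIN1 and LASP1 under HOPX (0.0617 and 0.0946), and TMM, the fit of 6 libraries and GC removal that of LASP1 (0.0559, 0.063 and 0.0805). The fit of 6 libraries ended MAD1L1 (0.0607), and removing both trends MCUB under GADD45B (0.0788) and IBTK under HOPX (0.107). Limma on log2(FPKM + 1) ended that of CFLAR under HOPX (0.0958). Pseudocounts of 0.1, 0.5 and 1 in limma gave the same counts (21, 18 and 13), a weak test since p-values moved by at most 0.167 on the log10 scale. Set tests with an estimated correlation, the pseudocount for the overexpressed genes and principal components of a larger set of variable genes were not run. The lists had under 5 tested members, those genes are not among the 99, and only 72 genes were tested. Depth limits the genes below the filter most: the log2 fold change of WNT16, at a mean of 17.3 counts, had an SE of 0.99.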

Other observations

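The tests of library length slopes, of scaling and of HOPX replicate 2 against GC content and of its label were chosen after the result was seen, as was the choice of genes in the next paragraph.

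Among the 27 genes below the expression filter, CYP26B1, a retinoic acid hydroxylase, was lower in GADD45B libraries (0.384 ± 0.0797 FPKM) than in WT (0.920 ± 0.244 FPKM) and in HOPX libraries (0.893 ± 0.0849 FPKM; SD, n = 3 each). In edgeR's quasi-likelihood test without the filter its log2 fold change was -1.25 against WT (SE 0.25, Benjamini-Hochberg adjusted p = 0.000348) and 1.21 for HOPX over GADD45B (SE 0.25, adjusted p = 0.000963). The initiator caspase gene CASP10, the other member of the pro-apoptotic group in the table, was at 0.748 ± 0.0434 FPKM under GADD45B against 1.13 ± 0.0140 in WT, a log2 fold change of -0.58 (SE 0.17, edgeR adjusted p = 0.00946). It was at 1.02 ± 0.172 FPKM under HOPX (-0.14, SE 0.17, edgeR adjusted p = 0.645). BAD and CASP10 were thus both lower under GADD45B than in WT. Without the filter, 23 of the 27 calls for GADD45B over WT were lower, so this says little about the pro-apoptotic group. The zinc finger gene ZNF195 was at -0.43 under GADD45B (SE 0.15, edgeR adjusted p = 0.0246) and -0.37 under HOPX (SE 0.15, adjusted p = 0.0823). WNT16, with a mean of 17.3 counts, was at -2.30 under GADD45B (SE 0.99) and did not pass edgeR's test (adjusted p = 0.0805).

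Genes with a longer exon length, such as KMT2E and MYCBP2, were lower against WT in both overexpression groups. For each library, the deviation of a gene's log2 level from its mean over the 9 libraries was fitted on log2 exon length. This relative slope was 0.09 to 0.10 in the WT libraries and -0.11 to 0.03 in the 6 overexpression libraries (two-sided exact permutation p = 0.0119, the smallest that 84 splits allow). It restates the pattern and does not tell its source. A straight-line trend of the libraries on log2 exon length is argued against as the whole cause. After its removal 20 of 25 calls under GADD45B and 11 of 17 under HOPX kept direction and threshold. Among them were SPPL2B, BAD, CROT, RECQL and KMT2E. A curved trend, or a trend on another measure of transcript length, was not tested. A trend on length remains a candidate explanation for DPM1 and CFLAR, whose log2 fold changes under HOPX went to 0.07 and -0.03, and for part of the change of MYCBP2 (-0.37 to -0.16) and FUCA2 (0.30 to 0.19) under GADD45B and HCCS (0.38 to 0.20) under HOPX, all 3 of which lost their calls. The slopes go with the groups, so a change in RNA integrity or library preparation and a change of long transcripts in the cells were not separated.

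HOPX over GADD45B gave only higher genes, and GADD45B over WT mostly lower ones, in edgeR's test. With median-of-ratios factors 50% of the calls were higher under HOPX in the former, and 61.54% of the calls were lower in the latter against 84% before. Those factors centre the median change of the same 72 genes, which brings the split toward balance in any case, so scaling and a real excess in 1 direction cannot be told apart in either comparison. BAD, CROT and SLC25A13 stayed past the threshold in both comparisons with these factors, whereas SPPL2B lost its HOPX over GADD45B call with them and with TMM scaling (edgeR adjusted p = 0.0799 and 0.0868). With quantile normalization, BAD, CROT and SLC25A13 lost their HOPX over GADD45B calls as well (limma adjusted p = 0.115, 0.0764 and 0.0542). Scaling on 72 genes and on library totals rest on different assumptions, and more genes would be needed to choose between them.

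HOPX replicate 2 departed from HOPX replicates 1 and 3, with less BAD (8.00 FPKM against 20.7 and 15.2) and less SPPL2B, and over the 72 genes it correlated better with GADD45B replicates 3 and 2 (r 0.992 and 0.990) than with them (0.987 and 0.985). The chi-square per gene of its counts ordered the libraries otherwise. It was 30.1 against GADD45B replicate 2, 35.9 against HOPX replicate 1, 42.1 against GADD45B replicate 3 and 59.3 against HOPX replicate 3. A WT library under this label is argued against: over the 20 genes past the threshold for HOPX over WT without this library, its median place between WT (0) and HOPX (1) was 0.991, against at most 0.0838 for WT libraries left out in turn. A GADD45B library under this label was neither shown nor excluded. The median place between GADD45B (0) and HOPX (1), over 20 genes chosen likewise, was 0.38. This was within the 0.01 to 0.57 of left-out GADD45B libraries and below HOPX replicates 1 and 3 (0.98 and 1.07, over 5 and 8 genes). Of the 20 genes, 13 lay outside the GADD45B libraries toward HOPX, but so did 11 of 14 for GADD45B replicate 2 left out. HOPX replicate 2 had more CROT (1.498 FPKM) and SLC25A13 (8.71 FPKM) than any GADD45B library (at most 0.873 and 6.61 FPKM). Both genes were named for HOPX over GADD45B only because these groups did not overlap in them. Their values were thus fixed by that selection and say nothing about the label. HOPX replicate 2 also lay higher than the GADD45B libraries on principal component 2 (0.61 against at most 0.12). Its SPPL2B (0.98 FPKM) lay among the GADD45B libraries. A GC-dependent library bias remains possible as well, as the departure fell with GC content across the 72 genes (Spearman -0.4403, permutation p = 0.0002). For BAD, whose SD of log2 level over the HOPX libraries was 0.699, removing the GC trend took it to 0.7055 of that value, between the bounds set in advance, so a library bias and a difference between the samples themselves cannot be told apart. BAD was also lowest in replicate 2 of the GADD45B group (4.11 FPKM) and of WT (9.31 FPKM). Relative slopes on GC content (log2 per percent) were 0.0039 to 0.0123 in replicates 1 and -0.0148 to -0.0017 in replicates 2. In replicates 3 they had both signs (-0.0062 to 0.0127). An effect shared by libraries of the same number thus cannot be told apart from these either.

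Other splits of the 6 libraries of each comparison gave fewer genes than the real one. Only the real split, 1 of 10, reached 25 genes for GADD45B over WT (highest other 0), 1 of 10 reached 17 for HOPX over WT (highest other 0) and 1 of 10 reached 12 for HOPX over GADD45B (highest other 5). With 10 splits the share cannot fall under 0.05.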
